A study of Mus musculus with 36 samples.

How the data were processed

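The series compared male C57Bl/6 mice carrying 1 inactivated copy of Myc (Myc+/-) with wild type males at 5 and 24 months of age, in liver, skeletal muscle and adipose tissue. Per the labels, RNA of the mice of a cohort was pooled in equal amounts, which gave 1 pool for each tissue, age and genotype, and each of the 12 pools was run on 3 technical arrays (Affymetrix Mouse Gene 1.0 ST, 36 arrays in all). A pool held RNA of 6 mice (wild type, 5 months), 5 mice (wild type, 24 months), 5 mice (Myc+/-, 5 months) or 8 mice (Myc+/-, 24 months), and the same 4 cohorts gave all 3 tissues. The labels name 2 ways of homogenizing tissue without saying which sample had which. They name a 3' IVT kit in one field and a whole-transcript kit in another, so the labelling chemistry is not settled here.

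The deposited values were log2 expression values per probe set, and Affymetrix Expression Console and RMA are named per the submitters' processing notes, with no version, role or settings given in the sources used here. The 36 arrays had medians near 7 on the log2 scale and nearly equal quartiles, as RMA with quantile normalization leaves them, and the values were used as deposited. Of 35556 probe sets, 23410 were listed in the annotation table that came with the values. Of these, 21789 had 1 gene symbol and 1621 had several, and 12146 were not listed and are unnamed here. For 21698 of the probe sets with 1 symbol the Entrez identifier was found in a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and gave the gene type, and 91 were not found. The genome build of the array annotation was not given, so no coordinates are printed.

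The arrays of a pool share 1 RNA mixture and are technical, so a pool was the replicate. The 3 arrays of each pool were averaged, and limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0) was fitted to the 12 pool means with a tissue, an age-within-tissue and a genotype-within-tissue term (9 coefficients, 3 residual degrees of freedom, 3.68 prior degrees of freedom, eBayes with an intensity trend). In this fit the difference between genotypes is averaged over both ages, and its error is how far that difference varied between the ages, shared over the 3 tissues. The age difference was likewise averaged over both genotypes. An effect of genotype on how a gene changes with age therefore enters the error of this fit. The genotype effect common to the tissues was fitted to the 6 differences between genotypes (5 residual degrees of freedom). Benjamini-Hochberg adjustment was applied within each comparison with a threshold of 0.05. Only probe sets with 1 symbol and a mean above the 40th percentile of such probe sets in the tissue were tested, which left 13073 per tissue and 11546 kept in all 3.

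A second limma fit used the 36 single arrays (24 residual degrees of freedom). It compares 2 RNA mixtures with array-to-array error alone, and cannot show a difference between the genotypes as populations. Probe sets with an adjusted p under 0.05 and at least a 1.5-fold difference are described as differing between pools. The p-values of the pool-level fit measure how far a difference varied between the ages or between the genotypes. They do not measure the spread between pools of like mice, since each tissue, age and genotype had 1 pool. The 3 residual degrees of freedom come from the same 4 cohorts in the 3 tissues, and the fit takes them as independent. The number of arrays bears on array-to-array error alone, whose median SD was 0.10 (log2) in liver, 0.10 in muscle and 0.09 in adipose. Further arrays of the same pools would not replace further pools.

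A set of 45 gene lists (971 entries, 878 matched to an array symbol) was tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, in the tissues each list was written for, and there for lists with at least 5 tested members. Camera compares a list with the other genes. The estimated correlation rests on the 3 residual degrees of freedom of the pool-level fit, so a list that misses with it is not shown to be unchanged. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The lists, the comparisons, the filter and the rule for named genes were fixed before the data were examined. Under that rule the text draws on the 10 genes in each direction with the largest change of 1 sign in both ages or both genotypes, ranked by the smaller of the paired differences, among those past the threshold and otherwise filled up without it. For the effect common to all tissues it takes 5 in each direction, for the difference in age change 5 in each direction per tissue, and for a list up to 4 members. Exceptions are said to have been chosen after their values were seen. A gene with several probe sets was represented by the one with the highest mean. The difference between 2 log2 values is a log ratio, and ± after a change gives the SE of the pool-level fit with 2 pools per arm.

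Each step was tested on simulated data with known changes in a seeded set of genes. For the genotype effect in liver, run on 13073 probe sets, the pool-level fit recovered 82.1% of simulated changes of 0.5 (log2), 98.5% of changes of 1 and 100% of changes of 2, and called 10 unchanged probe sets. For the age effect in liver it recovered 85.1%, 98.5% and 100%, and for the common effect 98.5%, 100% and 100%. With the minimum of 1.5-fold, which a change of 0.5 lies under, the single-array fit recovered 10.4% of changes of 0.5 and 100% of changes of 1 in 24-month liver, and 20.9% and 98.5% for the difference in age change in liver. With no minimum fold it recovered 88.1% and 76.1% of changes of 0.5. The simulated noise was independent between genes and pools, so these shares say nothing about shared differences between cohorts. They also do not bound what the real fit could miss, as many genes were changed at once and the noise used moderated variances. In the real liver fit Cidec, at 1.61 ± 0.24 (log2), did not pass (limma, adjusted p = 0.320). Alternatives covered the filter, the scaling between arrays, the variance model, single arrays as replicates, weights by number of mice, single tissues, a minimum fold and leaving out each pool or technical array. Without 1 pool, a difference in that tissue rests on 1 pair of pools, and its error comes from the other 2 tissues alone. Counts and calls without a pool are therefore no test on the tissue's own spread.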

Results

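Expression of 35556 probe sets was measured on 36 arrays of liver, skeletal muscle and adipose RNA from Myc+/- and wild type male mice of 5 and 24 months. The series title states that lowered Myc expression increased longevity and healthspan, and the arrays compare the genotypes within each tissue and age and the ages within each genotype. Each combination was 1 pool of 5 to 8 mice on 3 technical arrays. Array medians ran from 6.95 to 7.14 (log2), and the mean correlation of an array with the other arrays of its pool from 0.988 to 0.994. Across genes, pools of the 2 genotypes correlated at 0.995 to 0.996 and pools of the 2 ages at 0.982 to 0.989.

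Myc, which encodes a transcription factor that drives growth and ribosome production, read lower in the Myc+/- pool in each of the 6 pairs of pools. In liver it was 8.57 ± 0.13 in wild type and 7.97 ± 0.14 in Myc+/- at 5 months (log2, SD, n = 3 arrays), and 8.56 ± 0.04 and 8.32 ± 0.12 at 24 months. The Myc+/- level was 65.8% of wild type at 5 months and 84.8% at 24 months in liver, 71.5% and 56.6% in muscle, and 80.1% and 57.1% in adipose. Beyond array-to-array error, with no minimum fold, the difference in Myc passed in 5 of the pairs and missed in 24-month liver (limma, adjusted p = 0.0785). In 5-month muscle (-0.48) and 5-month adipose (-0.32) it was under 1.5-fold. At the pool level the difference in Myc was -0.42 ± 0.15 in liver, -0.65 ± 0.15 in muscle and -0.56 ± 0.15 in adipose, with adjusted p = 0.652, 0.924 and 0.444. Pvt1, the noncoding neighbour of Myc, read higher in Myc+/- pools in all 6 pairs, by 0.31 to 0.72 for its tested probe set. In 5-month muscle that difference was within array-to-array error (limma, adjusted p = 0.372). A second, dim Pvt1 probe set that was not tested differed by -0.07 to 0.15. The part of Myc that was inactivated relative to the probes was not given in the sources used here, so the level checks the labels and does not measure the loss of a working allele.

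**Figure D1:**
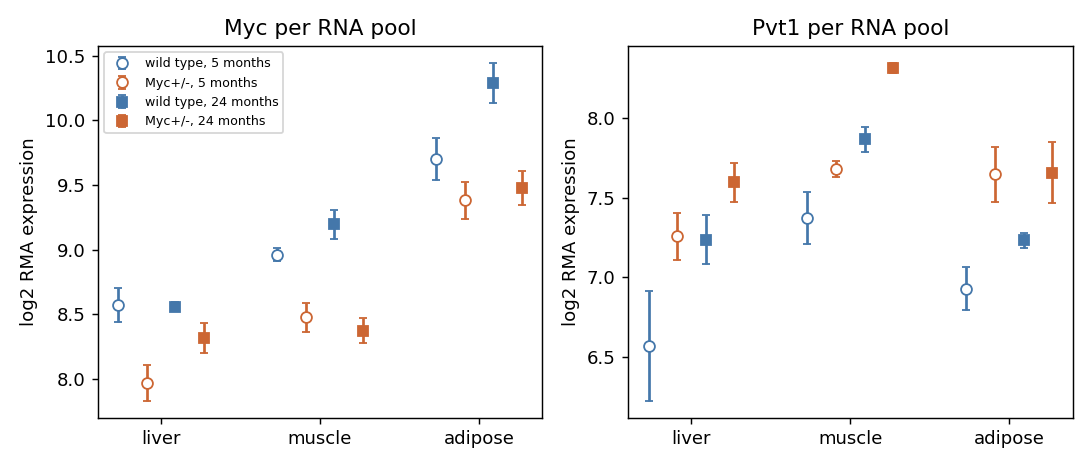
Log2 RMA expression of Myc (left) and Pvt1 (right) in the 12 RNA pools, by tissue, with open circles for 5 months, filled squares for 24 months, blue for wild type and orange for Myc+/-. Points are means and bars the SD of 3 technical arrays. Every Myc+/- pool lies below its wild type partner for Myc and above it for the tested Pvt1 probe set.

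In liver, Cidec, a lipid droplet protein, read higher in Myc+/- pools by 1.61 ± 0.24 (log2; 1.47 at 5 months and 1.75 at 24 months), and Cyp4a14, a fatty acid hydroxylase induced by PPAR alpha, by 0.88 ± 0.20. Mfsd2a, a lysophosphatidylcholine transporter, differed by 0.66 ± 0.10 and Nat8f5 by 1.17 ± 0.14. Socs2, a target of growth hormone signalling, differed by -0.68 ± 0.11, Tff3 by -0.77 ± 0.08 and the fast muscle light chain Myl1 by -1.19 ± 0.18. The fatty acid binding protein gene Fabp5 differed by -0.93 ± 0.23 (-0.41 at 5 months and -1.46 at 24 months). None of these passed at the pool level (limma, adjusted p = 0.217 to 0.558). Of 13073 probe sets 0 passed, the smallest adjusted p was 0.165, and 957 had an unadjusted p under 0.05 where 654 would by chance. Fitting liver alone called 17, among them Cidec.

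Cytosolic ribosomal protein genes read lower in Myc+/- liver for 26 of 27 members, with a median of -0.12 and Rps9 at -0.30 ± 0.09 and Rpsa at -0.28 ± 0.07 (camera adjusted p = 1.72e-12; adjusted p = 0.573 with an estimated correlation). Genes of fatty acid oxidation and PPAR alpha targets read higher for 24 of 24 members, with medians of 0.09 at 5 months and 0.26 at 24 months and Acot1 at 0.90 ± 0.35 (adjusted p = 6.69e-08; adjusted p = 0.573 with an estimated correlation). Without either 24-month pool that call was lost. Adjusted over the list alone 3 of these members passed, against 0 over all genes. Cholesterol synthesis genes had medians of 0.02 at 5 months and -0.31 at 24 months, with Lss, which closes the sterol ring, at -0.33 ± 0.16 (0.03 at 5 months and -0.70 at 24 months), and Myc targets of ribosome biogenesis had 0.04 and -0.13. Both calls (adjusted p = 4.16e-05 and 0.0371) were lost without either 24-month pool (adjusted p = 0.518), where the medians were 0.02 and 0.04, and had adjusted p = 0.573 and 0.849 with an estimated correlation. Interferon response genes read higher for 23 of 27 members (median 0.14, adjusted p = 1.52e-05) and proliferation genes for 17 of 17 (median 0.20, adjusted p = 1.52e-05), with adjusted p = 0.573 for both with an estimated correlation. The proliferation call was lost without either 24-month pool. Markers of cell types moved with these: macrophage genes read higher for 19 of 24 (median 0.12, adjusted p = 0.0322), neutrophil and myeloid genes for 9 of 9 (0.22, 0.0181) and adipocyte markers for 8 of 11 (0.17, 0.0155), with adjusted p = 0.849, 0.573 and 0.751 with an estimated correlation. These 3 calls were lost without either 24-month pool.

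Genes of other tissues moved with these groups. Skeletal muscle markers read lower in Myc+/- liver for 12 of 12 members (median -0.46), and 10 passed adjusted over the list alone, against 0 over all genes (camera adjusted p = 6.82e-17; adjusted p = 0.573 with an estimated correlation). Exocrine pancreas markers differed by a median of -0.11 at 5 months and 1.99 at 24 months (adjusted p = 1.38e-05; adjusted p = 0.573 with an estimated correlation), a list still called without either 24-month pool but with the sign turned (-0.11), and Cpa1, a pancreatic carboxypeptidase, was at 6.77 in both 5-month pools, 8.54 in wild type and 11.08 in Myc+/- liver at 24 months. The serum amyloid gene Saa1, of the acute phase response, was at 8.68 in wild type and 12.14 in Myc+/- at 5 months and at 12.40 and 8.45 at 24 months. Camera called 13 of 36 lists for genotype in liver, 7 of 33 in muscle and 9 of 31 in adipose. With an estimated correlation it called 0 in each tissue, and fry called 0.

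In muscle, genes of fatty acid and triglyceride synthesis read lower in Myc+/- pools for 20 of 22 members (median -0.21), with Fasn, the fatty acid synthase, at -0.83 ± 0.20 and Acaca at -0.66 ± 0.25 (camera adjusted p = 2.03e-07; adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone 2 passed, against 0 over all genes. Cish, an inhibitor of cytokine signalling, differed by -0.77 ± 0.10, and Pck1, which makes phosphoenolpyruvate, by -1.15 ± 0.26 (-0.55 at 5 months and -1.75 at 24 months). Genes of insulin, IGF1 and mTOR signalling read lower for 18 of 22 members, with Igf1 at -0.33 ± 0.12 and Irs1 at -0.28 ± 0.07 (adjusted p = 0.000336; adjusted p = 0.932 with an estimated correlation). Genes of denervation and the neuromuscular junction read higher for 13 of 14, with Ncam1 at 0.22 ± 0.08 and Musk at 0.21 ± 0.14 (adjusted p = 2.78e-05; adjusted p = 0.932 with an estimated correlation). Adipocyte markers read lower for 13 of 14 members, with medians of -0.04 at 5 months and -0.51 at 24 months, and macrophage genes for 21 of 21, with -0.02 and -0.48 (adjusted p = 2.03e-07 and 1.56e-06; adjusted p = 0.932 for both with an estimated correlation). The calls of insulin signalling, adipocyte and macrophage genes were lost without either 24-month pool.

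Epidermal and sebaceous genes moved with these in muscle: Serpina3b differed by -0.96 ± 0.18, Elovl4, which makes very long chain fatty acids, by -0.91 ± 0.17 and Defb6 by -1.30 ± 0.19. The skin keratin Krt5 was at 7.27 in wild type and 5.98 in Myc+/- muscle at 5 months and at 9.87 and 9.48 at 24 months. Albumin (Alb) was at 10.94 and 9.31 at 5 months and at 8.78 and 11.14 at 24 months. Adipoq, secreted by adipocytes, was at 10.29 and 10.34, then 12.33 and 11.14. Whether the lower Fasn, Acaca and Pck1 of Myc+/- muscle came from muscle fibres or from fat cells in the sample was not tested. Of 13073 probe sets 0 passed for genotype in muscle (limma, smallest adjusted p 0.731), with 611 at an unadjusted p under 0.05 where 654 would by chance. Genotype counts without a pool are not given, since muscle would then keep 1 pair of pools and no spread of its own.

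In adipose, Fam183b, a gene of ciliated cells, fell by 2.11 ± 0.14 (log2; -1.82 at 5 months and -2.40 at 24 months) and was the 1 probe set of 13073 that passed for genotype (limma, adjusted p = 0.0278). It missed the threshold without either 24-month pool (-1.82), with adipose fitted alone and with all probe sets tested, and the 60th percentile filter removed it. Mmp7, a matrix protease of epithelia, differed by -1.97 ± 0.39 (-0.99 at 5 months and -2.95 at 24 months), Plet1 by -1.68 ± 0.27 and Adgrg2, a receptor of the male genital tract, by -0.71 ± 0.08. Kap, an androgen-regulated kidney gene, differed by 1.86 ± 0.34 (1.01 at 5 months and 2.70 at 24 months), the immunoglobulin gene Igha by 1.21 ± 0.39, Mogat2, which makes diacylglycerol, by 1.08 ± 0.11, and the imprinted gene Peg10 by 0.95 ± 0.15, with no call. At an unadjusted p under 0.05 there were 1051 probe sets where 654 would be expected by chance. Genotype counts without a pool are not given here either.

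Cholesterol synthesis and uptake genes read higher in Myc+/- adipose for 18 of 20 members (median 0.25), with Insig1, a sterol sensor, at 0.61 ± 0.16, Fdps at 0.45 ± 0.08 and Nsdhl at 0.39 ± 0.10 (camera adjusted p = 9.49e-06; adjusted p = 0.693 with an estimated correlation). Adjusted over the list alone 8 passed upward and 1 downward, against 0 over all genes. Oxidative phosphorylation genes read lower for 33 of 35 (median -0.12, Cox7b -0.25 ± 0.06) and ribosomal protein genes for 26 of 27 (median -0.10), with adjusted p = 9.11e-11 and 5.26e-09. Interferon response genes read higher for 24 of 27 (median 0.12) and senescence and p53 targets for 12 of 14 (median 0.13, Cdkn2b 0.31 ± 0.10), with adjusted p = 0.00113 and 0.0156. All of these had adjusted p = 0.693 with an estimated correlation. The interferon call was lost without either 24-month pool and the senescence call without either 5-month pool. Hepatocyte markers read higher in Myc+/- adipose for 10 of 10 members, by a median of 1.23 at 5 months and 0.34 at 24 months (adjusted p = 0.0104; adjusted p = 0.693 with an estimated correlation), a call lost without either 5-month pool. Alb was at 9.93 in wild type and 11.47 in Myc+/- at 5 months. The sperm protamine Prm1 was at 7.47 and 7.06 at 5 months and at 8.45 and 11.63 at 24 months. Genotype effects differed between tissues for 0 of 11546 probe sets in each of the 3 pairs of tissues (limma, 591, 636 and 672 at an unadjusted p under 0.05).

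Averaged over the tissues, Myc itself differed by -0.55 ± 0.08 (SE, 6 pairs of pools), Pvt1 by 0.49 ± 0.06, the small nucleolar RNA Snora74a by -0.40 ± 0.06, the imprinted gene Nnat by -0.40 ± 0.10, Cish by -0.41 ± 0.10 and the interferon-induced chemokine Cxcl10 by 0.62 ± 0.16. Each had 1 sign in all 6 pairs, as had 510 of 10503 genes (4.86%, where chance gives 3.13% for independent pairs). The 6 pairs came from 4 cohorts whose mice gave all 3 tissues, so the SE and this chance value take as independent what is not. Of 11546 probe sets 0 passed (limma, smallest adjusted p 0.193), with 938 at an unadjusted p under 0.05 where 577 would by chance.

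At each age taken alone, the Myc+/- and wild type pools differed beyond array-to-array error and by at least 1.5-fold at 60 probe sets in liver at 5 months (49 higher in Myc+/-) and 237 at 24 months (141 higher). In muscle these were 56 (3 higher) and 203 (35 higher), and in adipose 179 (146 higher) and 157 (74 higher). Acute phase genes gave 7 of the 45 genes higher in 5-month Myc+/- liver and 10 of the 90 lower at 24 months. Exocrine pancreas markers gave 10 of the 139 genes higher at 24 months. Of the 53 genes lower in 5-month Myc+/- muscle, 18 were epidermal or sebaceous and 7 hepatocyte markers, and of the 160 lower at 24 months, 8 made fatty acids or triglycerides, 7 were adipocyte markers and 6 macrophage genes. Hepatocyte markers ran the other way at 24 months, with 6 of the 35 genes higher in Myc+/- muscle. Of the 135 genes higher in 5-month Myc+/- adipose, 10 were hepatocyte markers, 7 acute phase genes, 6 inflammatory cytokines and chemokines and 5 macrophage genes. At 24 months 5 of the 69 genes higher in Myc+/- adipose made fatty acids or triglycerides, macrophage genes gave 1 of these and 6 of the 80 lower, and acute phase genes 1 and 2. The epidermal list was written after the data had been seen. Probe sets differing the same way at both ages numbered 6 higher and 3 lower in liver (0.528 and 0.0808 expected for independent lists), 0 and 4 in muscle (0.00803 and 0.681), and 15 and 10 in adipose (0.826 and 0.210). In opposite directions, either order counted, 12, 14 and 16 differed, with no expected value computed. That was more than the sum of the same-way counts in liver and muscle, but less than their sum in adipose. Each genotype had 1 pool per tissue and age, so the overlap is not read as a genotype effect held at both ages. Across genes the genotype difference at 5 months correlated with that at 24 months, which came from other mice, at -0.0163 in liver (0.0450 by Spearman), 0.0648 in muscle and 0.122 in adipose. Genes are not independent replicates, and no p is given.

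**Figure D2:**
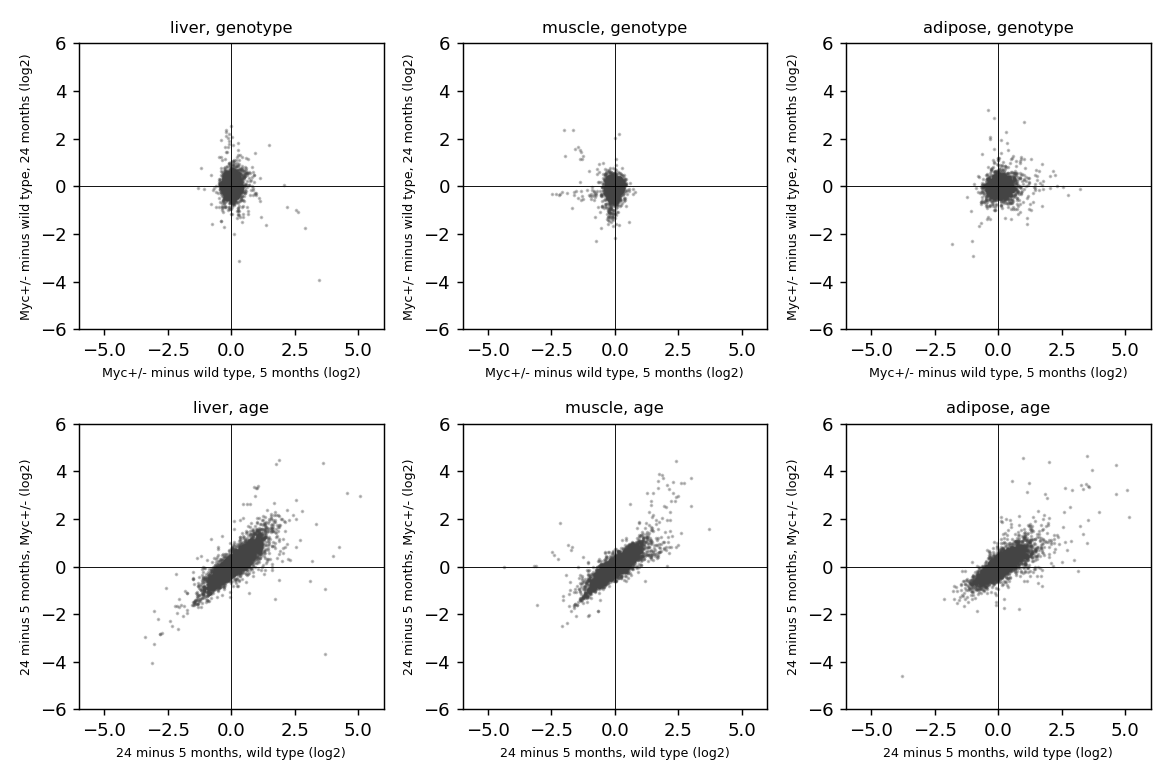
Each point is 1 of 13073 probe sets per tissue. The top panels set the Myc+/- minus wild type difference (log2) at 24 months against that at 5 months, with r of -0.0163, 0.0648 and 0.122, and the bottom panels set the 24 minus 5 month difference in Myc+/- pools against that in wild type pools, with r of 0.818, 0.839 and 0.773.

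Immune genes were higher and clock genes lower in 24-month liver. Ngp, a neutrophil granule protein, rose by 3.99 ± 0.22 (log2), the B cell chemokine gene Cxcl13 by 2.55 ± 0.22, Ccl5 by 1.97 ± 0.26 and the immediate early gene Egr1 by 1.99 ± 0.07. All 9 neutrophil and myeloid genes rose, as did 22 of 24 macrophage genes (Cd53 1.76 ± 0.17, Itgam 1.54 ± 0.15), and 21 of 27 interferon response genes rose while 1 fell (Irf7 2.10 ± 0.14, Rsad2 1.76 ± 0.10). Proliferation genes rose for 12 of 17, led by Mki67 at 1.46 ± 0.20. Male-biased liver genes fell for 12 of 21 (Moxd1 -3.59 ± 0.20, Hsd3b5 -1.73 ± 0.37), and female-biased genes rose for 8 of 13 (Cyp2b9 1.67 ± 0.35, Abcd2 1.11 ± 0.19). The calls of these lists had adjusted p = 0.654 to 0.694 with an estimated correlation.

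Clock genes fell for 12 of 18 in liver and rose for 2, with Ciart at -3.18 ± 0.19, the output gene Dbp at -2.46 ± 0.28 and Per3 at -1.79 ± 0.12. The hour of sacrifice was not given in the sources used here. Oxidative phosphorylation genes fell for 25 of 35 and rose for 3 (Ndufb8 -1.10 ± 0.08), fatty acid and triglyceride synthesis genes fell for 9 of 22 and rose for 1 (Thrsp -2.35 ± 0.26, Srebf1 -1.11 ± 0.07) and cytosolic ribosomal protein genes for 14 of 27 (Rps19 -1.21 ± 0.05). Collagen and matrix genes rose for 15 of 28 (Thbs1 1.59 ± 0.09). Adjusted over the list alone, 23 macrophage genes and 22 interferon genes rose, and 12 clock genes and 27 oxidative phosphorylation genes fell. Camera called 16 of 36 lists for age in liver, among them each of these, with adjusted p = 0.654 to 0.715 with an estimated correlation. Fry called 14 of the 16 and missed fatty acid synthesis and exocrine pancreas genes. The calls of proliferation and matrix genes were lost without either Myc+/- pool and that of the female-biased genes without either wild type pool. Exocrine pancreas markers rose with these for 8 of 10 members (Cpa1 3.03 ± 0.50). Small nucleolar RNAs, a class picked out after the values had been seen, fell for 34 of 42 (median -0.91, Snora74a -3.15 ± 0.11). In liver 6125 of 13073 probe sets passed for age (3924 higher), and 1550 of them by at least 1.5-fold. Without the 5-month or the 24-month wild type pool the counts were 3211 and 3217.

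In muscle, slow fibre genes fell for 9 of 12 members and rose for 1, with the slow myosin light chain Myl2 at -1.73 ± 0.15 and the slow troponin Tnnc1 at -1.64 ± 0.17. Collagen and matrix genes fell for 11 of 31 and rose for 1 (Col1a1 -1.30 ± 0.14, Col3a1 -0.87 ± 0.08), oxidative phosphorylation genes fell for 19 of 35 and rose for 3 (Ndufa5 -1.11 ± 0.08), and ribosomal protein genes fell for 12 of 28 and rose for 2 (Rpl13 -1.20 ± 0.06). Interferon response genes rose for 18 of 25 (Irf7 1.52 ± 0.14), B and plasma cell genes for 5 of 6 (Jchain 1.82 ± 0.07), and translation factors for 11 of 20 while 3 fell (Eif5a 1.39 ± 0.07). Clock genes fell for 8 of 18 and rose for 3 (Ciart -1.06 ± 0.19), a call lost without either wild type pool. Each of these list calls had adjusted p = 0.664 with an estimated correlation.

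Genes of skin and fat rose with these in muscle. The skin genes Elovl4 (3.37 ± 0.17), Serpina3b (3.11 ± 0.18), Krt5 (3.05 ± 0.21) and the desmosomal cadherin Dsc3 (2.72 ± 0.13) were among the 10 highest by the rule for named genes. Adipocyte markers rose for 10 of 14, with Retn at 1.66 ± 0.18, Adipoq at 1.42 ± 0.25 and Plin1 at 1.20 ± 0.23. Small nucleolar RNAs fell for 27 of 39 and rose for 2 (median -0.59). Adjusted over the list alone, 20 interferon genes and 10 adipocyte markers rose, and 9 slow fibre genes and 19 oxidative phosphorylation genes fell. Camera called 9 of 33 lists, with adjusted p = 0.664 for each with an estimated correlation. Fry called 5 of the 9 and missed clock, matrix, slow fibre and adipocyte genes. In muscle 5357 probe sets passed for age (2975 higher), and 1150 by at least 1.5-fold. Without the 5-month wild type, 24-month wild type, 5-month Myc+/- or 24-month Myc+/- pool the counts were 2066, 2075, 2804 and 2808.

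In adipose, all 11 B and plasma cell genes rose, with Jchain at 3.29 ± 0.07, Ighm at 2.45 ± 0.16 and the B cell receptor component Cd79a at 2.39 ± 0.22, and the light chain gene Igkv4-91 rose by 4.44 ± 0.13. T and NK cell genes rose for 12 of 14 (Cd3g 1.72 ± 0.09, Nkg7 1.75 ± 0.24), macrophage genes for 20 of 25 (Gpnmb 1.70 ± 0.40) and interferon response genes for 24 of 27 (Ifit1 1.52 ± 0.09). Vsig4, a macrophage complement receptor, rose by 3.46 ± 0.19. Adipocyte markers fell for 5 of 14 (Lep, the gene of leptin, -0.81 ± 0.15), oxidative phosphorylation genes for 18 of 35 (Ndufb3 -0.92 ± 0.11) and clock genes for 11 of 18 while 1 rose (Ciart -1.75 ± 0.19). Glycolysis and gluconeogenesis genes fell for 6 of 16, with Pfkfb3 at -1.02 ± 0.13 and the insulin-regulated glucose transporter Slc2a4 at -0.42 ± 0.07. These list calls had adjusted p = 0.394 to 0.566 with an estimated correlation.

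Cytosolic ribosomal protein genes rose in adipose for 13 of 27 (median 0.20), and small nucleolar RNAs rose for 20 of 36 (median 0.37). The sperm genes Smcp (3.19 ± 0.47) and Prm1 (2.77 ± 0.70) rose beside these, with Smcp at 5.68 in wild type and 5.36 in Myc+/- at 5 months and at 7.68 and 9.75 at 24 months. Adjusted over the list alone, 11 B cell genes, 24 interferon genes and 22 macrophage genes rose, and 22 oxidative phosphorylation genes and 6 adipocyte markers fell. Camera called 17 of 31 lists for age in adipose, with adjusted p = 0.394 to 0.717 with an estimated correlation. Fry called 8 of the 17 and missed, among others, macrophage, oxidative phosphorylation and adipocyte genes. In adipose 3405 probe sets passed for age (1574 higher), and 805 by at least 1.5-fold. Without the 5-month wild type, 24-month wild type, 5-month Myc+/- or 24-month Myc+/- pool the counts were 544, 543, 1491 and 1490.

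**Figure D3:**
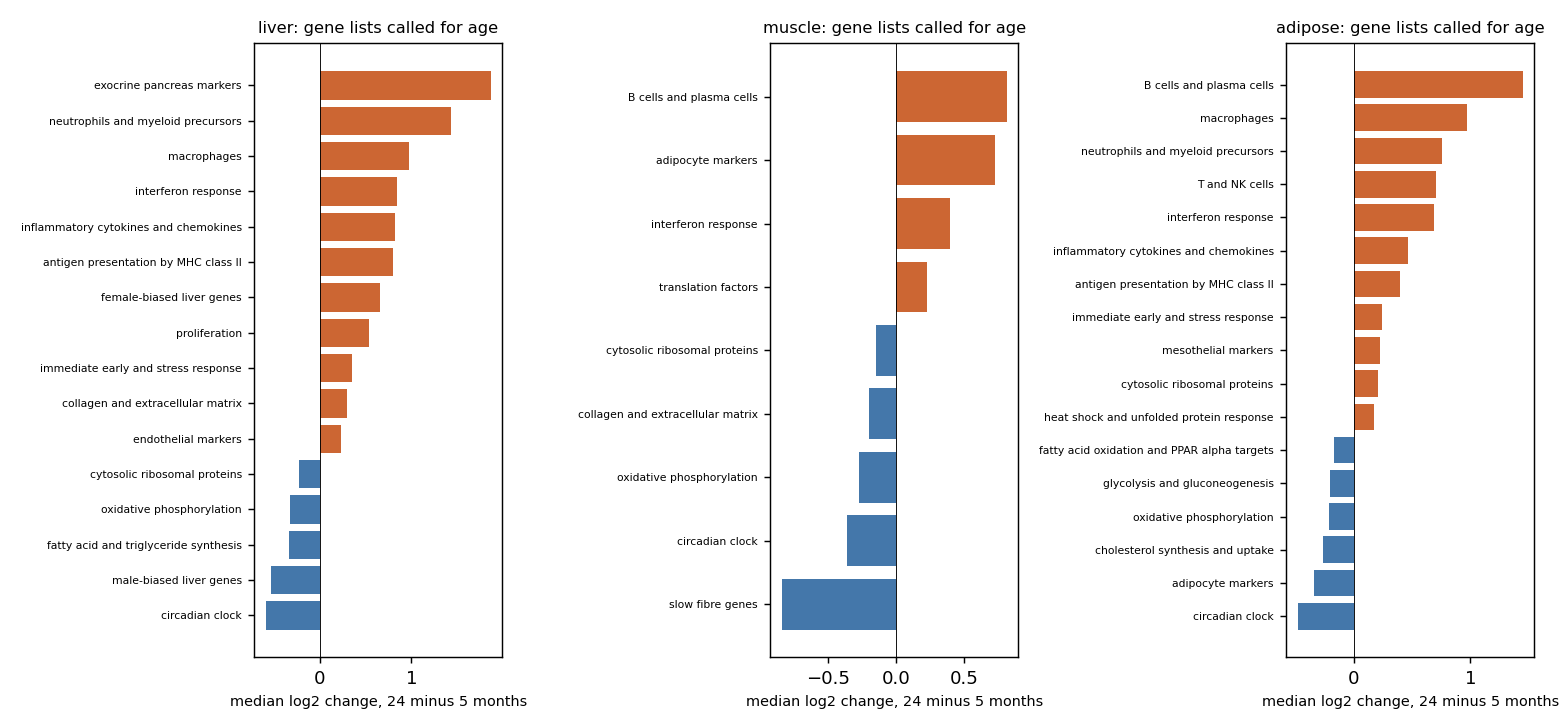
Median log2 change (24 minus 5 months, averaged over both genotypes) of the members of each gene list called for age by camera with the preset correlation in liver, muscle and adipose; orange bars are lists called higher and blue bars lists called lower. Clock and oxidative phosphorylation genes lie below 0 and interferon genes above 0 in all 3 tissues, and none of the calls held with an estimated correlation.

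In liver, acute phase genes led the genes whose change with age differed between the genotypes. Saa1 changed by 3.71 between the wild type pools and by -3.69 between the Myc+/- pools, a difference of -7.40 ± 0.22 (SE from single arrays), and Orm2, an acute phase plasma protein, changed by 3.11 and -0.61. The pancreatic gene Cpa1 changed by 1.77 in wild type and 4.30 in Myc+/- liver. In muscle the hepatocyte gene Alb changed by -2.16 and 1.83 and the macrophage chemokine gene Ccl8 by 2.07 and 0.01, and in adipose Prm1 changed by 0.97 and 4.57 and the macrophage elastase gene Mmp12 by 1.74 and -0.81. These differences between pools passed at 318 probe sets in liver, 253 in muscle and 354 in adipose (limma on single arrays, at least 1.5-fold), and show how the 4 pools of a tissue differ, with 1 pool in each arm.

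Over the probe sets called for age, the slope of the Myc+/- change on the wild type change (total least squares) was 0.964 in liver, 0.940 in muscle and 0.857 in adipose. The change was smaller in the Myc+/- pools for 58.2%, 57.1% and 65.1% of these, with a median difference of -0.04, -0.02 and -0.06. Simulations of equal change gave slopes of 0.974 to 1.01, 0.978 to 1.01 and 0.966 to 1.03, with noise independent between genes, which makes these ranges too narrow for differences shared by many genes. The slopes have no test. Of the lists that camera called for age, the median change was smaller in the Myc+/- pools for 6 of 16 in liver, 5 of 9 in muscle and 13 of 17 in adipose. In adipose, macrophage genes had medians of 1.25 in wild type and 0.69 in Myc+/- pools, in muscle slow fibre genes had -1.21 and -0.45, and in liver antigen presentation genes of MHC class II had 0.35 and 1.24, examples chosen after their values were seen.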

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

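The tests of dim probe sets, small RNAs and epidermal genes, and the comparison of age changes between tissues, were chosen after the patterns had been seen, with bounds set before the deciding values were computed, and the limit to brighter small RNAs was chosen after their medians had been seen.

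The change with age differed between tissues beyond the error of the pool-level fit (limma, adjusted p under 0.05, over 11546 probe sets) at 1081 probe sets for liver against muscle, 3860 for liver against adipose and 4176 for muscle against adipose. Liver and muscle shared 2980 age calls in 1 direction where 1178 would be expected for independent lists, liver and adipose 1022 against 655, and muscle and adipose 657 against 583. Calls that ran in opposite directions, counted only where the difference between the tissues also passed, numbered 149, 563 and 740, with no expected value computed. Even under this stricter rule muscle and adipose had more of these than shared ones. Across genes the age changes correlated at 0.618, 0.293 and 0.0437. Snord33 changed by -1.87 in liver, -0.92 in muscle and 1.16 in adipose.

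The shared age change of liver and muscle has technical and biological candidates. A processing difference between the 5-month and the 24-month arrays would move dim probe sets, which carry little tissue signal, together in both tissues. Over 6170 dim probe sets the age change in wild type liver correlated with that in Myc+/- muscle, from other mice, at 0.251, between the bounds of 0.1 and 0.3 set beforehand, and a block of 998 unlisted probe sets, whose nature is not given here, gave 0.464 and 0.549 for liver and muscle of other mice against 0.584 and 0.547 over tested genes, so this stays open, while dim probe sets gave 0.00458 to 0.114 in the pairs with adipose. A loss of small RNAs with age in every tissue is argued against by adipose, where small nucleolar RNAs changed by a median of 0.369 (0.37 on the log2 scale). Age itself, the storage of frozen tissue and the unassigned homogenization methods remain possible and were not tested.

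Small nucleolar RNAs read lower in the Myc+/- pools, with medians of -0.15 in liver (37 of 42 lower), -0.26 in muscle (38 of 39) and -0.23 in adipose (32 of 36), though none passed alone. Lower recovery of all small RNAs in the Myc+/- pools would lower the other classes too. Among members above the 60th percentile, other small RNAs lay closer to no change in 3 of 3 tissues. Their medians were -0.13 against -0.18 in liver, -0.01 against -0.27 in muscle and -0.08 against -0.24 in adipose (permutation p = 0.0400, 0.000650 and 0.00788, genes taken as independent). Without microRNA genes the other 11 or 12 had medians of -0.15, -0.11 and -0.14 (permutation p = 0.470, 0.0761 and 0.185). The contrast therefore rests on the microRNA genes, and lower recovery of small RNAs, or of some of their classes, stays open. Whether the difference follows the axis separating the ages in liver and muscle also stays open, since the adipose median of -0.233 was lower than that of liver, but it was -0.08 at 5 months, against -0.16 in liver, and -0.41 at 24 months. The lower Myc of these mice remains an open candidate that the design confounds with the 4 cohorts.

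Epidermal and sebaceous genes were higher in 24-month muscle. Of the list's members not seen before it was written, 90% (18 of 20) passed upward, with a median change of 1.47, and abundant skin genes such as Krt10 reached 10.19 in wild type and 9.98 in Myc+/- muscle at 24 months against 8.76 and 7.22 at 5 months. Skin in the dissected tissue is a hypothesis for the rise of these genes. An age change of these genes in every tissue is argued against by liver and adipose, where 1 of the 11 members that were also tested there passed upward (9.09%), and the medians were -0.14 in liver (8 members) and 0.02 in adipose (11). A change within muscle fibres was not tested and stays open.

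The difference in age change between the genotypes passed at 318 probe sets in liver, 253 in muscle and 354 in adipose, each a difference between pools on single arrays. Of 100 draws of genotype labels among the 6 arrays of each age, the real one included, 1 in liver, 2 in muscle and 1 in adipose called as many. Mixing technical arrays of different pools adds the difference between pools to the error, so mixed splits had to call fewer. The draws therefore decide nothing about chance or about differences between cohorts. The split that exchanges the genotypes at 1 age was drawn in muscle alone. The highest other counts were 303, 297 and 283. Splits that keep the genotypes apart at 1 age gave up to 303, 238 and 283, and the count of 297 came from exchanging the genotypes at 1 age. Splits that mix the arrays at both ages gave at most 3, 10 and 13, low counts that the layout of technical arrays brings about.

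Probe sets without a listed gene entered none of the main comparisons. For age, 2141 of 5456 tested passed in liver (956 higher), 1865 of 5386 in muscle (754 higher) and 664 of 5434 in adipose (373 higher).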

How the results depend on the processing

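The alternatives with a minimum of 1.5-fold at the pool level, without small RNA, ribosomal protein and epidermal genes, and with median centring for gene lists were chosen after seeing the data. Unless a construction is named (fewer genes, pools or arrays, a stricter fold), the cause was not tested.

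None of the genes ranked by the rule for named genes reversed under the alternatives run, but that rule takes genes of 1 sign in both ages or genotypes, so leaving out a pool could not turn them. Of 116 list members named for genotype, 14 had opposite signs at the 2 ages, so leaving out a pool turns some of these, and of 168 named for age 0 had opposite signs in the 2 genotypes. All 71 list calls ended with an estimated correlation, and fry ended 29 of 29 for genotype and 15 of 42 for age. The correlation was estimated from 3 residual degrees of freedom, and with it camera called 0 lists in each tissue, for age as for genotype. A miss with it is therefore no evidence that a list was unchanged, nor does it uphold the preset call. A simulated list shifted by 0.3 (log2) in liver did pass with it (camera, adjusted p = 0.0125), under noise independent between genes. Fry called 22 lists for age in liver, 11 in muscle and 9 in adipose. Reversed medians came only from leaving out a 24-month or 5-month pool, which leaves the difference at the other age: in liver the range was -0.132 to 0.0421 for Myc target ribosome biogenesis, -0.307 to 0.0235 for cholesterol synthesis and uptake and -0.114 to 1.99 for exocrine pancreas markers, in muscle -0.0186 to 0.0851 for oxidative phosphorylation, and in adipose -0.0160 to 0.282 for fatty acid and triglyceride synthesis and -0.00161 to 0.175 for collagen and extracellular matrix.

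Genotype counts of 0 in liver, 0 in muscle, 1 in adipose and 0 in common became 1026, 506, 1148 and 758 with single arrays as replicates, which understates the error by construction. Fitting each tissue alone gave 17 in liver and 0 in adipose, the robust fit gave 5 in adipose, and the 60th percentile filter and all probe sets gave 0 there. Leaving out a pool gave 0 to 22 in liver, 9 to 45 in muscle and 0 to 17 in adipose, with fewer pools by construction. Leaving out a technical array gave 0 to 1 in liver and 1 to 3 in adipose.

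Age counts became 8070 in muscle and 6481 in adipose with single arrays. A minimum of 1.5-fold gave 1550, 1150 and 805 in liver, muscle and adipose. Leaving out a pool or a technical array gave 3211 to 5524, 2066 to 5059 and 543 to 3073, with the fewest calls without a pool. The share of higher calls went from 46.2% to 34.6% in adipose with median centring and from 64.1% to 53.5% in liver with quantile normalization within tissue. No scaling moved the median change by over 0.1 (log2).

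The replicate numbers were not taken to pair the arrays, since deviations of arrays with the same number correlated at only 0.0102, -0.00153 and 0.00671 on average. Not every array correlated best with its own number, but 20 of 36 did, where shuffled numbers gave 12.1 on average and as many in 1.5% of 1000 shuffles. The mean correlation was reached in 22% of the shuffles. This is a hint from the data of some shared array effect, which the labels do not name. With the replicate number as a block, single arrays gave genotype counts of 1034 in liver, 506 in muscle, 1159 in adipose and 739 in common, and age counts of 8087 in muscle and 6520 in adipose. The block moved no count of differences between pools by over 1.5 times.

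Differences between pools with no minimum fold numbered 564 and 2006 in liver (5, then 24 months), 166 and 1242 in muscle and 1543 and 1092 in adipose, and 1215, 625 and 933 for the difference in age change in liver, muscle and adipose. At 2-fold they numbered 15 and 66, 28 and 61, and 53 and 44, and 80, 70 and 110. Without the filter 5-month muscle gave 118, 5-month and 24-month adipose 286 and 403, and the difference in age change 410 in muscle and 617 in adipose. With the 60th percentile filter 24-month liver gave 142, 5-month muscle 23, 5-month and 24-month adipose 97 and 81, and the difference in age change 188, 164 and 214.

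For the genotype difference in liver, r between the ages was 0.0252 without the filter, 0.0450 by Spearman and -0.0609 to 0.00727 without 1 technical array, so its sign is not settled. For the genotype difference in muscle, r was 0.0221 without the filter, 0.108 at the 60th percentile, 0.143 by Spearman and 0.0189 to 0.0842 without 1 technical array, and in adipose 0.0687 to 0.134 without 1. For the age difference, r between the genotypes was 0.769 and 0.873 in muscle under these filters and 0.669 and 0.819 in adipose, 0.740 in adipose by Spearman, and 0.807 to 0.831 in muscle and 0.743 to 0.762 in adipose without 1 array. The slope of the age change was 0.870 in muscle and 0.779 in adipose by least squares, which shrinks slopes by construction, and 0.825 in adipose over all tested probe sets. Probe sets near background limit what the arrays can show, and genes below the 40th percentile were not tested.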

Other observations

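Genes that moved with age in all 3 tissues were chosen after their values were seen. They numbered 233 higher and 235 lower of 11546 probe sets, where 87.7 and 50.0 would be expected for independent lists, which these are not, as the tissues share cohorts. Among the higher were immunoglobulin and B cell recruitment genes (Igha 1.90 in liver, 2.70 in muscle and 3.47 in adipose; Cxcl13 2.55, 1.77 and 3.45) and interferon genes (Irf7 2.10, 1.52 and 1.13; Rsad2 1.76, 1.29 and 0.92). Among the lower were clock genes (Bhlhe41 -1.70, -0.75 and -1.01; Per3 -1.79, -0.59 and -0.87), Higd1a, a mitochondrial protein of the hypoxia response (-0.69, -0.90 and -0.70), and the alanine aminotransferase gene Gpt (-1.10, -0.52 and -0.67).

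Other genes ran in opposite directions between tissues with age, also chosen after their values were seen. Fasn changed by -0.94 ± 0.20 in liver and 1.45 ± 0.20 in muscle, the stress gene Gadd45a by -0.68 ± 0.11 and 0.68 ± 0.11, and its relative Gadd45b by 0.87 ± 0.18 and -0.81 ± 0.18. The adipocyte gene Adipoq rose in the same muscle pools, from 10.29 to 12.33 in wild type and from 10.34 to 11.14 in Myc+/-. Whether the rise of Fasn came from muscle fibres or from fat cells in the sample was not tested. Prg4, the gene of lubricin, changed by 0.82 ± 0.27 in liver, -1.03 ± 0.27 in muscle and 1.68 ± 0.27 in adipose. The imprinted gene Mest changed by 0.85 ± 0.15 in liver and -1.11 ± 0.15 in adipose, and the skin gene Cdsn by 1.12 ± 0.12 in muscle and -1.25 ± 0.12 in adipose. In adipose, chaperone and unfolded protein genes rose for 9 of 20 members (Sdf2l1 0.64 ± 0.09, Creld2 0.62 ± 0.16), and of 12 mesothelial markers 5 rose and 1 fell (Wt1 0.92 ± 0.09, Msln -0.38 ± 0.10). Both lists had camera calls that ended with an estimated correlation (adjusted p = 0.420 and 0.517), and that of the mesothelial markers was lost without either Myc+/- pool.

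Antigen presentation genes of MHC class II rose for 6 of 7 members in 24-month liver (Cd74 1.30 ± 0.22), immediate early genes for 8 of 16 (Jun 1.15 ± 0.07), endothelial markers for 8 of 16 (Tek, a receptor of angiopoietin, 0.64 ± 0.10) and cytokine genes for 9 of 16 (Ccl6 1.70 ± 0.13). All of these were camera calls, which had adjusted p = 0.654 to 0.694 with an estimated correlation, and the first 3 were lost without either Myc+/- pool. In 24-month adipose, cytokine genes rose for 9 of 17 (Ccl8 3.14 ± 0.56), and cholesterol synthesis genes fell for 5 of 20 (Sc5d -0.54 ± 0.10), where the estimated correlation gave adjusted p = 0.420 and 0.584. Fatty acid oxidation genes fell for 9 of 22 and rose for 1 there (Cpt2 -0.52 ± 0.06, Pdk4 1.28 ± 0.13), a call lost without any 1 of the 4 adipose pools (adjusted p = 0.717 with an estimated correlation).

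The other lists that camera called for genotype had small medians. In liver, antioxidant genes of NRF2 and glutathione read higher in Myc+/- pools for 14 of 20 members (median 0.07, adjusted p = 0.0475) and mesothelial markers lower for 8 of 9 (-0.14, 0.0161), both with adjusted p = 0.573 with an estimated correlation and both lost without either 5-month pool. In muscle, oxidative phosphorylation genes read higher for 29 of 35 (0.04, adjusted p = 0.0135) and MHC class II genes lower for 5 of 5 (-0.30, 0.0218), with adjusted p = 0.976 and 0.932 with an estimated correlation and both lost without either 24-month pool. In adipose, fatty acid and triglyceride synthesis genes read higher for 17 of 22 (0.14, adjusted p = 0.0104), cytokine genes for 15 of 17 (0.19, 0.0109) and collagen and matrix genes for 27 of 31 (0.08, 0.00688), each with adjusted p = 0.693 with an estimated correlation. The fatty acid call was lost without either 24-month pool and the other 2 without either 5-month pool.

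The 6 differences between genotypes beyond array-to-array error were set against all 10 splits of the 6 arrays of each pair of pools, too few for a share under 0.05. The real split gave 60, 237, 56, 203, 179 and 157 probe sets (liver, muscle and adipose, 5 then 24 months), 1 of the 10 splits in each case, and the highest other split 1, 3, 0, 18, 0 and 0. For the genotype effect common to the tissues, 32 of 32 exchanges of the labels within tissue and age called as many as the real 0 (highest other 0), a count that could not come out otherwise and decides nothing. At an unadjusted p under 0.05 the real labels gave 938 and the highest other 839, 1 of 32. The tissues share 4 cohorts, and exchanges within 1 tissue break that link, so this leaves a difference between cohorts as it is.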
